A study of Mus musculus and Gallus gallus with 9 samples.

How the data were processed

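Hearts of ICR mouse embryos at embryonic day 11.0 and of chick embryos at Hamburger-Hamilton stage 18 were separated by region (AVC, OFT, VEN) and tissue of a region was pooled over hearts. Per the labels, RNA was extracted with phenol and chloroform, its integrity was checked on a Bioanalyzer, and libraries were made with neither normalization nor fragmentation of RNA or cDNA. Mouse had 2 libraries per region and chick 1, 9 in all. The submitters' processing notes name TopHat2, TopHat and the mouse build mm9. Tool versions, the read counter, its annotation and strand setting, and the chick genome build are not given in the sources used here.

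The deposited tables hold counts, as whole reads per listed gene or transcript name, and these were the input here. Beside them the authors give CPM values, each count divided by its library's total and scaled to a common total. The ratio columns, as deposited by the authors, hold the fold between libraries, blank where neither library reached 10 reads. The deposited p-value columns hold the authors' p-values between single libraries, made by a test that is not given in the sources used here. Those authors' columns were described but not used for any comparison. The recomputed CPM differed from the authors' values by at most 5e-06. The replicate number of the mouse columns was taken from the name of the table that holds them.

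The mouse tables listed 29595 names. Of these 15898 were current gene symbols, 4189 older symbols, 139 symbols in other case and 9369 matched no symbol, and the unmatched names, which took 7 to 7.7% of the reads, were kept in the fit. Where several names led to a symbol (973 symbols), the one with the highest mean was kept, leaving 28580 features. Symbols came from tables of current and older gene names, and transcript length and GC content, used only in checks, from GENCODE vM21. Of 17778 chick names 6100 were matched to 6078 mouse genes, 171 of them by the deposited description, and no genome annotation of the chick was used.

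Mouse regions were compared in edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, R 4.3.3) with region as the only term and all 6 libraries in 1 fit, so that the 3 regions shared an estimate of the spread. There were 3 residual degrees of freedom and the biological coefficient of variation was 0.242. Features passed at a Benjamini-Hochberg adjusted p under 0.05 over the 14881 tested, two-sided. The replicate number was not a term, since the labels do not say that a number marks a shared pool or day. Yet across genes each AVC library correlated more with VEN of its number (r = 0.9739 and 0.9737) than with the other AVC library (0.9591). OFT libraries did not (0.9475 and 0.9576 with VEN, 0.9617 with each other). What libraries of a number share thus enters the spread of this fit. In simulated counts of the AVC and VEN comparison with this spread, edgeR recovered 88% of genes changed 4-fold and 12% of those changed 2-fold with 14 false calls, and DESeq2 1.42.0 recovered 92% and 26% with 30. Simulations used the same number of genes as the fit, with 100 genes changed at each size. The changed genes were drawn from those with a mean of at least 5 CPM. Libraries were drawn independently, without any deviation shared by libraries of a replicate number, so these rates hold for that setting only. Groups of 2 libraries allow neither a permutation of labels with a useful p nor a test for a library apart from its group.

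For the 31 gene lists (776 entries, 712 distinct genes, 688 matched in mouse and 444 in chick), members past the threshold were counted over all genes and adjusted over the list alone. Each list was tested by camera in limma 3.58.1 with its preset correlation, with an estimated correlation, and by fry, adjusted over the 93 tests of 31 lists in 3 comparisons. By camera 56 tests passed. With an estimated correlation 0 passed (27 at an unadjusted p under 0.05, smallest adjusted p 0.0739), and by fry 27, of which 26 were among the 56. With the replicate number as a block 0 passed by fry (smallest adjusted p 0.0591) and 57 by camera. Several lists share members. The lists, the rule for named genes, the test, its terms and most alternatives were chosen before the data were examined. The rule names, per mouse comparison and direction, the 10 genes with a symbol and a mean of at least 5 CPM that passed with the same sign in both replicates and had the largest fold, filled by the largest statistics where fewer passed. It also names per chick comparison and direction the 8 with the largest fold, and of each list the first member and those with the largest fold. A single gene that the rule names in the AVC versus OFT comparison is not reported here. Genes outside the rule are said to be named after their values were seen.

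In chick, values were scaled by TMM, 1 CPM was added before ratios were taken, and genes with at least 20 reads over the libraries compared were kept, with 95% intervals of a ratio from exact binomial limits on its reads. A list's median was placed among 10000 random lists matched on expression. Their genes were drawn singly, so these lists do not allow for members that move together. Mouse and chick folds were compared by rank correlation and by sign, with 1000 permutations of the chick folds within 20 bins of expression.

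In mouse 3 reads over a group, the most that a count of 0 allows, stand for 0.177 CPM in AVC, 0.157 in OFT and 0.16 in VEN, and in chick 3 reads stand for 0.29 to 0.333. A group at 0 was set to that floor for a ratio that leaves out the counting error of the other group. Alternatives tried were other scaling, filters, tests, row handling, thresholds, priors, the replicate number as a block, fits of 4 libraries and leaving out each library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.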

Results

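RNA was sequenced from 3 regions of the embryonic heart tube in mouse and chick: the atrioventricular canal (AVC), the outflow tract (OFT) and the ventricles (VEN). The AVC and OFT carry the endocardial cushions, tissue swellings that later form valves and septa. They fill with mesenchyme when endocardial cells undergo an epithelial-to-mesenchymal transition (EMT), while the ventricles are mainly chamber muscle lined by endocardium. Mouse hearts were from ICR embryos at embryonic day 11, pooled by region (160 hearts per the labels, which leave open whether this is per replicate), in 2 libraries per region. Chick hearts were at Hamburger-Hamilton stage 18, pooled by region (200 hearts), in 1 library per region. In mouse the tables listed 7209279 and 9961270 reads for the AVC libraries (replicate 1, then replicate 2), 7085154 and 12743480 for OFT and 5784365 and 13724538 for VEN. In chick they listed 9019757 reads for AVC, 9977225 for OFT and 10361849 for VEN. Haemoglobin genes took 1.23 to 3.34% of the mouse reads, with a higher share in replicate 1 than in replicate 2 of every region, and 1.34, 2.59 and 3.98% of the chick AVC, OFT and VEN reads. Across mouse genes, which are not independent replicates, the difference between the replicate 1 and replicate 2 libraries of a region correlated with that of another region (r = 0.548 to 0.65 over the 3 pairs of regions).

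The comparison of AVC with VEN asks which genes mark the cushion-bearing canal against chamber tissue without such cushions. In mouse, Wnt9b, a Wnt ligand, was 21.3-fold higher in the AVC (log2 fold change 4.41 ± 0.46 SE, n = 2 libraries per region, adjusted p = 0.0184), at 12.4 ± 0.805 CPM (mean ± SD) in AVC and 0.52 ± 0.241 in VEN. Rspo3, a secreted amplifier of Wnt signalling, was 13.3-fold higher (log2 3.74 ± 0.32, adjusted p = 0.0184), and Twist1, a transcription factor of mesenchymal cells, was 11.5-fold higher (log2 3.52 ± 0.40, adjusted p = 0.024). Bmp2, a ligand required for AVC cushion formation, was 8.89-fold higher, at 43.1 ± 7.45 against 5.07 ± 2.72 CPM (adjusted p = 0.0341). Of the chamber muscle genes, Nppa, which encodes atrial natriuretic peptide, was lower in the AVC by 5.62-fold (646.6 ± 204.6 against 3634 ± 986.5 CPM, adjusted p = 0.0336). Gja5, which encodes the gap junction protein connexin 40, was lower by 3.59-fold (log2 -1.84 ± 0.25, adjusted p = 0.0336).

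**Figure D1:**
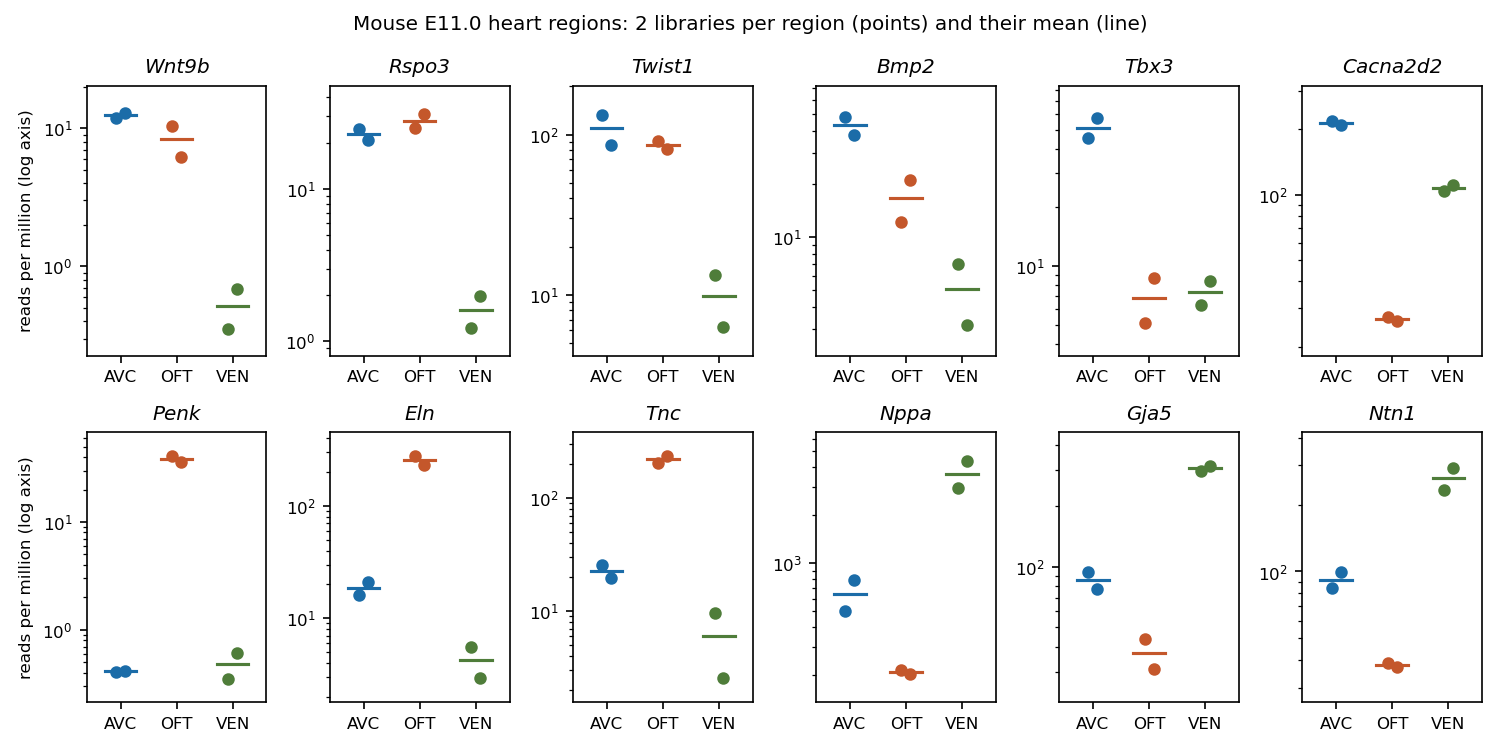
CPM (log axis) of 12 genes in the mouse AVC, OFT and VEN, with points for the 2 libraries per region and a line at their mean. Mean Wnt9b was 12.4 in AVC and 0.52 in VEN, mean Eln was 253.7 in OFT and 4.26 in VEN, and mean Nppa was highest in VEN at 3634.

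The other large increases in the AVC were in Tmem132c (15.3-fold), Cthrc1, which encodes a secreted collagen-associated protein (13.1-fold), and the carbonic anhydrase gene Car3 (10.4-fold). They were followed by Bmper, which encodes a secreted BMP-binding protein (10.3-fold), Papss2, whose enzyme makes the sulfate donor used for proteoglycans (9.76-fold), and the homeobox gene Prrx1 (9.4-fold), with adjusted p between 0.0184 and 0.0453. The 3 other named decreases were Wdr93 (4.58-fold), Mab21l2 (3.59-fold) and Ntn1, which encodes the guidance protein netrin-1 (2.87-fold). As 5 of the genes that fell had a symbol, the named decreases were filled with 5 genes that did not pass by edgeR without a block, though all 5 passed with the replicate number as a block (adjusted p at most 3.64e-06): Hand1, 5.93-fold lower in AVC (adjusted p = 0.0738), Cited1, 2.81-fold (0.0909), Casq2, 2.33-fold (0.126), Kcnk3, 2.26-fold (0.111), and the myoglobin gene Mb, 2.26-fold (0.0777).

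By gene group, 6 of the 30 cushion mesenchyme and EMT genes rose in the AVC and none fell (17 and 0 when adjusted over the list alone). Besides Twist1 and Prrx1 these were Msx1, a homeobox gene induced by BMP (6.45-fold), Sox9, a regulator of cartilage and valve matrix (4.47-fold), and, named after their values were seen, Postn (6.11-fold) and Has2 (3.72-fold). The list's median log2 fold change was 0.84 (adjusted p = 2.09e-34 by camera, adjusted p = 0.0739 with an estimated correlation), and 25 members were higher in both replicates. Of 34 collagen, elastic fibre and proteoglycan genes 6 rose (13 adjusted over the list alone), among them Papss2, Col9a1 (8.13-fold) and Eln, which encodes elastin (4.61-fold). The median was 0.45 (adjusted p = 2.67e-21, and adjusted p = 0.0739 with an estimated correlation). Of 30 Wnt signalling genes 4 rose (12 adjusted over the list alone): Wnt9b, Rspo3 and, named after their values were seen, the Wnt target Axin2 (4.3-fold) and the Wnt antagonist gene Frzb (3.69-fold). Their median was 0.59 (adjusted p = 5.2e-17, and adjusted p = 0.0739 with an estimated correlation). Of 36 BMP and TGF-beta genes Bmper and Bmp2 rose (13 rose and 3 fell when adjusted over the list alone). The median was 0.30 (adjusted p = 1.63e-07, and adjusted p = 0.0739 with an estimated correlation). Of 17 AVC myocardium and conduction genes 4 rose (7 adjusted over the list alone): Rspo3, Bmp2, the T-box repressor Tbx2 (7.79-fold) and its relative Tbx3 (6.89-fold, named after its values were seen). That list had the highest median of these groups, 0.99 (adjusted p = 4.18e-22, and adjusted p = 0.0739 with an estimated correlation).

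Of 29 chamber myocardium genes, Nppa and Gja5 fell and none rose (6 fell and 3 rose when adjusted over the list alone). The median was -0.31 (adjusted p = 4.54e-06, and adjusted p = 0.12 with an estimated correlation). The 37 endothelial and endocardial genes had a median of -0.44 (adjusted p = 7.81e-08, and adjusted p = 0.314 with an estimated correlation). Of them 30 were lower in the AVC in both replicates, and none passed by itself by edgeR or when adjusted over the list alone, while 15 fell with the replicate number as a block. Pecam1, an endothelial adhesion gene, was at 104.4 ± 23.9 CPM in AVC and 154.4 ± 20.6 in VEN (adjusted p = 1). The erythroid list moved with them. The median was -0.33 (adjusted p = 0.0114, and adjusted p = 0.543 with an estimated correlation), with replicate medians of -0.08 and -0.77. Its call ended without VEN replicate 1, and without AVC replicate 2 its direction turned. Such fits set a single replicate number of a region against both numbers of the other. Haemoglobin genes took a higher share in replicate 1 of every region, so these fits cannot tell region from replicate number.

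In all, 57 genes were higher and 6 lower in the AVC among 14881 tested by edgeR at an adjusted p under 0.05. With the replicate number as a block the numbers were 489 and 262. Without it the calls all went in the same direction in both replicates, with a median absolute log2 fold change of 2.49. In that fit 846 genes were at an unadjusted p under 0.05 by edgeR. The count of calls for the mouse AVC versus VEN without a block moved with the libraries used. It was 0 without OFT replicate 1, without OFT replicate 2, without VEN replicate 2 or with only the 4 AVC and VEN libraries (905, 885, 497 and 833 at an unadjusted p under 0.05). It was 11 without VEN replicate 1 and 20 without AVC replicate 2, while DESeq2 on all 6 libraries called 180. Such p-values measure only the spread between these libraries, since nothing in the sources used here says that the pools were of separate litters.

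The OFT also carries cushions, which receive neural crest cells as well as endocardial mesenchyme, and its comparison with VEN asks the same question for this region. Eln was 62.5-fold higher in the OFT (log2 5.97 ± 0.37, n = 2 libraries per region, adjusted p = 0.00117), at 253.7 ± 30.3 CPM against 4.26 ± 1.9 in VEN. Penk, which encodes the opioid precursor proenkephalin, was 72.0-fold higher (log2 6.17 ± 0.35, adjusted p = 0.00117). Mybpc1, a myosin-binding protein gene known from slow skeletal muscle, was 63.3-fold higher (log2 5.98 ± 0.37, adjusted p = 0.00117), and the homeobox gene Meox1 42-fold (log2 5.39 ± 0.35, adjusted p = 0.00117). Tnc, which encodes the matrix protein tenascin C, was 39.1-fold higher, at 220.0 ± 19.4 against 6.08 ± 5.01 CPM (adjusted p = 0.00452). Nppa was 17.4-fold lower (209.3 ± 6.6 against 3634 ± 986.5 CPM, adjusted p = 0.00259), Gja5 8.26-fold lower (log2 -3.05 ± 0.26, adjusted p = 0.00259) and Ntn1 6.96-fold lower (adjusted p = 0.00259).

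The remaining named increases were in Stmn4 (23.6-fold), Cthrc1 (22.5-fold), Dlg2 (20.7-fold), Col9a1, a chain of type IX collagen (20.6-fold), and Baalc (20.3-fold). The remaining named decreases were in the SRY-related gene Sox3 (10.3-fold), Tmem163 (7.43-fold), the lysozyme genes Lyz2 (6.03-fold) and Lyz1 (4.64-fold), Art1 (5.69-fold), Scube2 (5.25-fold) and the homeobox gene Irx2 (5.1-fold). Lyz1 and Lyz2 are near-identical in sequence, and how reads matching both were counted is not given in the sources used here. Penk and Mybpc1 had 10 and 6 reads over both VEN libraries, against 723 and 406 over the OFT libraries.

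Of 19 outflow tract and second heart field genes 7 rose and none fell (13 and 1 when adjusted over the list alone). The median was 1.74 (adjusted p = 4.3e-12, and adjusted p = 0.12 with an estimated correlation). Isl1, a transcription factor of second heart field progenitors, was 45.2-fold higher (log2 5.50 ± 0.86, adjusted p = 0.0216) with 186 reads over the OFT and 4 over the VEN libraries. Nkx2-6, a homeobox gene, had 53 reads in OFT and 0 in VEN (adjusted p = 0.036 by edgeR). It was at least 13.6-fold higher by the lower limit of its 95% interval, and 17.4-fold against a floor of 3 reads over the group. Tlx1 and Tbx1 also had 0 reads in VEN. By that limit they were at least 10.2-fold and at least 6.72-fold higher (13.1-fold and 8.85-fold against the floor). They did not pass by edgeR (adjusted p = 0.0535 and 0.0761, and 1.21e-05 and 0.000286 with the replicate number as a block). The list's median stayed at 1.74 with these genes at their values against the floor, which leave out the counting error of the OFT reads. Such limits and the counting intervals given for low counts cover counting error only. Of 14 cardiac neural crest genes 4 rose, the crest and glial regulator Sox10 (18.4-fold by its 56 reads in OFT against 3 in VEN, 95% interval 5.97 to 91.7), the retinoic acid-binding protein gene Crabp1 (13.3-fold), Sox8 (10.8-fold) and Erbb3 (8.94-fold). Sox8 and Erbb3 were named after their values were seen, as was Ednrb, which fell (log2 -1.59 ± 0.22). When adjusted over the list alone 6 rose and 1 fell, and the median was 0.70 (adjusted p = 4.54e-06, and adjusted p = 0.137 with an estimated correlation). Camera also called this list higher in AVC versus VEN (median 0.20, adjusted p = 0.00261, and 0.225 with an estimated correlation), where Sox10 had 24 reads in AVC. In AVC versus OFT no member passed by edgeR, and the median was -0.41 (adjusted p = 0.000311 by camera, and 0.12 with an estimated correlation).

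Of 30 cushion mesenchyme and EMT genes 13 rose in the OFT and none fell (20 and 1 when adjusted over the list alone), with Prrx1 at 15.3-fold, Postn, which encodes the matrix protein periostin, at 9.75-fold, Twist1 at 9.09-fold and Sox9 at 4.56-fold. The median was 1.18 (adjusted p = 2.36e-23, and adjusted p = 0.104 with an estimated correlation). Of 34 collagen, elastic fibre and proteoglycan genes 12 rose and none fell (20 and 0 when adjusted over the list alone). The median was 0.97 (adjusted p = 5.15e-26, and adjusted p = 0.0739 with an estimated correlation). Of 30 Wnt genes 8 rose (15 rose and 4 fell when adjusted over the list alone), with the Wnt antagonist gene Dkk1 at 31.8-fold, Rspo3 at 16.4-fold and Wnt9b at 14.1-fold. The median was 0.87 (adjusted p = 6.11e-11, and adjusted p = 0.094 with an estimated correlation). Of 36 BMP and TGF-beta genes 8 rose and 4 fell (15 and 4 when adjusted over the list alone). Bmper was 13.5-fold higher, while the receptor gene Bmpr1b was 8.11-fold, the BMP antagonist gene Chrdl1 7.5-fold and the ventricular ligand gene Bmp10 4.11-fold lower. The median was 0.29 (adjusted p = 0.00249, and adjusted p = 0.126 with an estimated correlation).

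Of 29 chamber myocardium genes 8 fell in the OFT and none rose (13 and 1 when adjusted over the list alone). The median was -0.71 (adjusted p = 1.15e-13, and adjusted p = 0.0739 with an estimated correlation). Of 37 endothelial and endocardial genes 4 fell (11 fell and 2 rose when adjusted over the list alone), among them the natriuretic peptide receptor gene Npr3 (2.99-fold). The median was -0.36 (adjusted p = 6.02e-06, and adjusted p = 0.364 with an estimated correlation). None of the 35 sarcomere genes passed by edgeR (17 fell and 2 rose with the replicate number as a block), and their median was -0.39 (adjusted p = 0.00301, and adjusted p = 0.364 with an estimated correlation). No erythroid gene passed by edgeR either (2 fell when adjusted over the list alone, and 14 with the replicate number as a block), and the median of the 18 was -0.60 (adjusted p = 2.89e-05, and adjusted p = 0.424 with an estimated correlation). Smooth muscle genes went the other way, with Rgs5 (4.54-fold) and Tagln (2.95-fold) higher in the OFT and a median of 0.46 over 16 genes (adjusted p = 0.0152, and adjusted p = 0.442 with an estimated correlation). That call ended without OFT replicate 1 (adjusted p = 0.0937) or without VEN replicate 2 (0.162). The AVC myocardium list went both ways, with Isl1, Rspo3 and Tbx2 (3.7-fold) up and Tbx5 (4.59-fold) and, named after their values were seen, Hcn4 (log2 -1.56 ± 0.24) and Cacna2d2 (log2 -2.0 ± 0.20) down (5 up and 4 down when adjusted over the list alone, adjusted p = 0.192 by camera). The stress and dissection response list had a median of 0.39 (adjusted p = 0.00326, and adjusted p = 0.364 with an estimated correlation) with no member past the threshold by edgeR and 3 higher when adjusted over the list alone, while 11 rose and 1 fell of its 23 members with the replicate number as a block. Markers of foregut epithelium, which lies next to the OFT, summed to 4.06 and 6.39 CPM in the OFT libraries to 4.62 and 3.82 in the VEN libraries and to 9.98 and 10 in the AVC libraries.

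In all, 258 genes were higher and 87 lower in the OFT by edgeR (1396 and 1103 with the replicate number as a block). The 345 called without a block all went in the same direction in both replicates, with a median absolute log2 fold change of 2.09. Of these 345 genes 71 passed without OFT replicate 1, 50 without OFT replicate 2 and 69 without VEN replicate 2, the count was 124 without VEN replicate 1, and DESeq2 called 599 on all 6 libraries.

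The direct comparison of the cushion-bearing regions asks what sets AVC and OFT apart. Cacna2d2, a calcium channel subunit gene, was 7.91-fold higher in the AVC (log2 2.98 ± 0.21, n = 2 libraries per region, adjusted p = 0.00352), at 212.8 ± 7.31 against 26.9 ± 0.902 CPM. Tbx3 was 7.28-fold (log2 2.86 ± 0.33, adjusted p = 0.0257) and Tbx5, a T-box activator of the inflow and chambers, 4.4-fold higher (log2 2.14 ± 0.21, adjusted p = 0.0182). Higher in the OFT were Penk (90.6-fold, adjusted p = 0.00166), Mybpc1 (38.9-fold, adjusted p = 0.00326), Eln (13.6-fold, log2 -3.76 ± 0.32, adjusted p = 0.0117) and the elastic fibre gene Fbln5 (11.1-fold, adjusted p = 0.019). Penk and Mybpc1 had 7 and 9 reads over both AVC libraries.

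Also higher in the AVC were Ap3b2 (15.8-fold), Lyz1 (6.12-fold), Irx2 (5.91-fold), Pirt (5.24-fold) and Gpr22 (4.64-fold), and Sox3, 4.57-fold higher, filled the list without passing (adjusted p = 0.0557, and 8.97e-09 with the replicate number as a block). The other named genes higher in the OFT were Psd (10.2-fold), Rgs5, a gene of pericytes and smooth muscle (8.43-fold), Meox1 (7.57-fold), Masp1 (7.32-fold), the neural adhesion gene L1cam (6.94-fold) and the Wnt modulator gene Sfrp2 (6.74-fold). Of the 17 AVC myocardium and conduction genes, Cacna2d2, Tbx3 and Tbx5 rose (8 rose and 1 fell when adjusted over the list alone). The median was 0.95 (adjusted p = 1.04e-12, and adjusted p = 0.0739 with an estimated correlation). Among the atrial myocardium genes only Tbx5 passed, 9 of 17 rose when adjusted over the list alone, and the median was 0.85 (adjusted p = 2.49e-11, and adjusted p = 0.0739 with an estimated correlation). Irx2 was among the 29 chamber myocardium genes that were tested as a list (9 rose and 1 fell when adjusted over the list alone). The median was 0.23 (adjusted p = 4.38e-09, and adjusted p = 0.0998 with an estimated correlation). Of 19 outflow tract and second heart field genes, Rgs5 fell (9 fell when adjusted over the list alone). The median was -0.51 (adjusted p = 2.43e-15, and adjusted p = 0.0739 with an estimated correlation). Of 34 matrix genes, Eln and Fbln5 fell (10 fell when adjusted over the list alone). The median was -0.42 (adjusted p = 6.31e-10, and adjusted p = 0.094 with an estimated correlation). Of 30 cushion mesenchyme and EMT genes, the matrix gene Tgfbi (3.76-fold) and the chemokine gene Cxcl12 (4.01-fold) were lower in the AVC, also when adjusted over the list alone. The median was -0.07 (adjusted p = 0.0393, and adjusted p = 0.465 with an estimated correlation). That call ended without AVC replicate 1 (adjusted p = 0.263), without OFT replicate 2 (0.412) or without VEN replicate 2 (0.0512). Twist1, Sox9 and Wnt9b did not pass in this comparison, with Sox9 at 140.4 ± 14.2 CPM in AVC and 143.2 ± 1.68 in OFT (adjusted p = 1).

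In all, 9 genes were higher in the AVC and 18 in the OFT by edgeR (909 at an unadjusted p under 0.05), all in the same direction in both replicates. With the replicate number as a block 444 were higher in the AVC and 503 in the OFT. In the mouse AVC versus OFT none of the 27 passed without OFT replicate 1 or without OFT replicate 2, where the count was 0 (593 and 1448 at an unadjusted p under 0.05). The count was 10 without AVC replicate 1 and 16 without AVC replicate 2, and DESeq2 called 139 on all 6 libraries.

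The cushion-bearing regions had in common 50 genes higher than VEN in both AVC and OFT, among them Wnt9b, Rspo3, Cthrc1, Twist1, Prrx1, Bmper, Papss2, Col9a1, Sox9 and Eln. Tissue was pooled by region, so these genes are not assigned to the cushions or to another tissue of the regions. A further 6 genes were lower in both, among them Nppa, Gja5 and Ntn1, and 0 genes passed in opposite directions by edgeR. Independent lists of these sizes would share 0.988 and 0.0351 genes. With the replicate number as a block 390 genes were higher and 194 lower in both, against 45.9 and 19.4 for independent lists. Both comparisons use the VEN libraries, so the lists are not independent, and the overlap that this alone would give lists of these sizes was not estimated. Simulated unchanged regions that shared VEN called almost no genes (mean overlap 0.1 higher and 0.04 lower genes in 50 simulations), which does not give that value. The 50 became 0 without OFT replicate 1, without OFT replicate 2, without VEN replicate 2 or in fits of only the 4 libraries compared. They became 9 without VEN replicate 1 and 17 without AVC replicate 2, while DESeq2 gave 115.

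**Figure D2:**
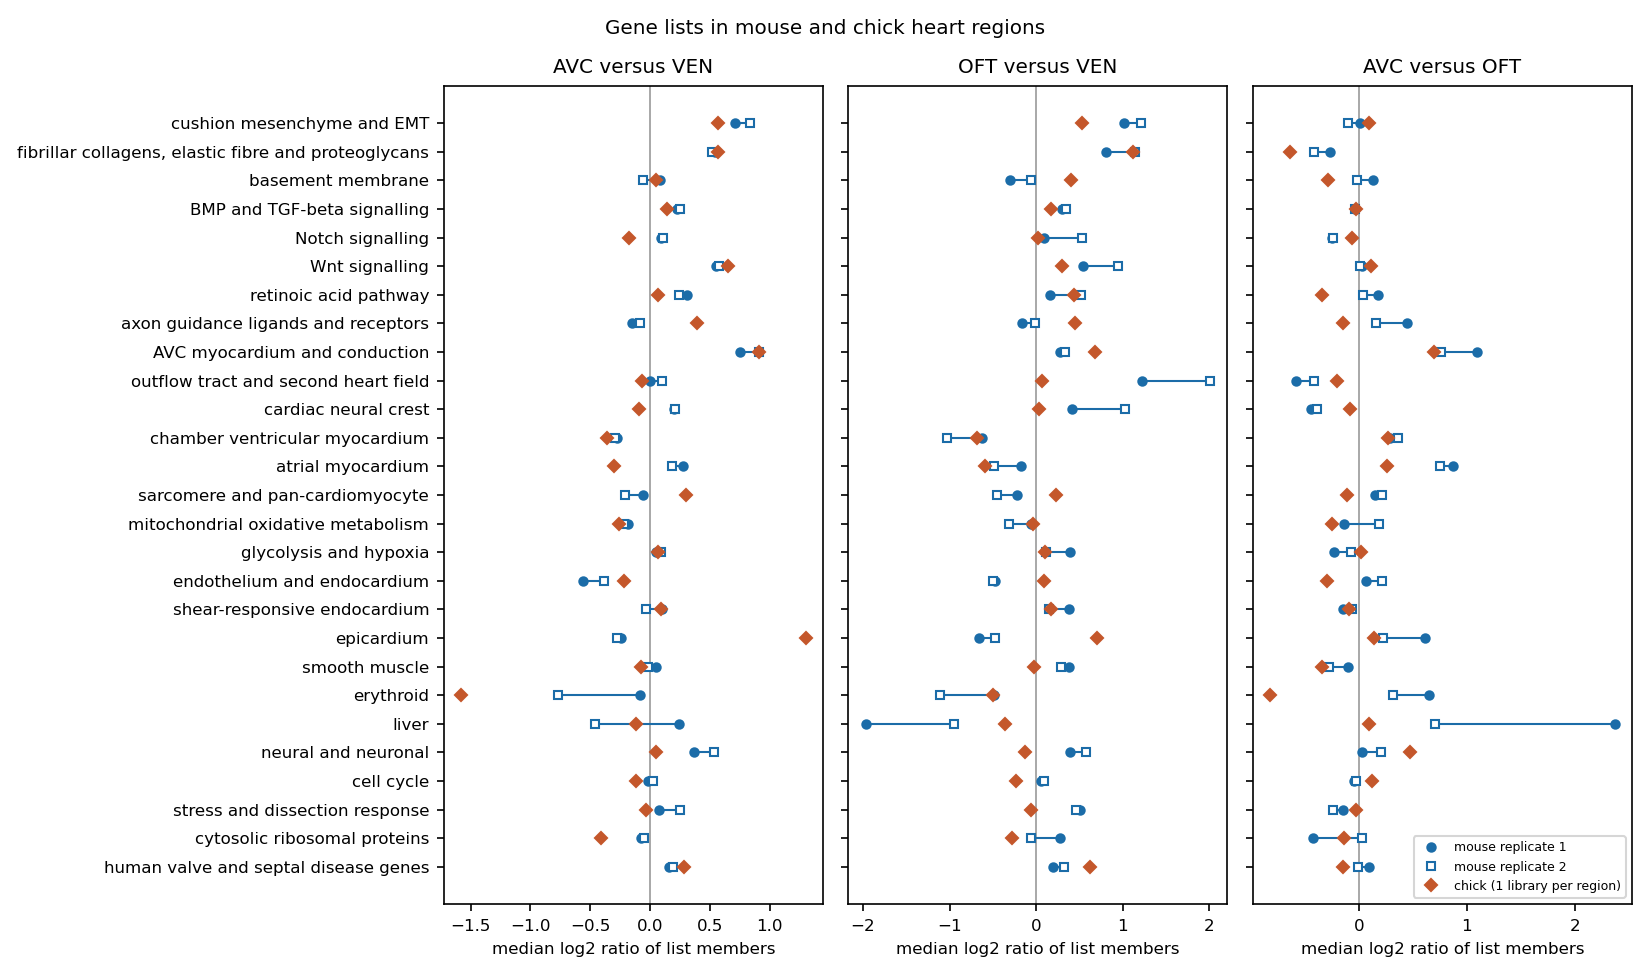
Median log2 ratio (horizontal axis) of each of 27 gene lists with at least 5 measured members in every comparison, as points for the 2 mouse replicates and for the chick library, in AVC versus VEN, OFT versus VEN and AVC versus OFT. For the cushion mesenchyme and EMT list the AVC versus VEN medians were 0.71 and 0.83 in the mouse replicates and 0.57 in chick.

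In chick, SOX9, RSPO3, BMP2 and TBX2 were among the 8 genes with the largest ratio of AVC over VEN. With 1 library per region these values are sizes only, given as ratios of scaled CPM after adding 1 to each, for genes with at least 20 reads over both libraries. SOX9 was 12.7-fold higher (318 reads in AVC, 17 in VEN), RSPO3 10.5-fold (485 and 39 reads), BMP2 8.46-fold (144 and 9 reads) and TBX2 6-fold (163 and 20 reads). The others were FAM5C (11.4-fold), the matrix genes THBS2 (7.48-fold) and LAMA2 (7.38-fold), and CDH11, which encodes a mesenchymal cadherin (7.25-fold). NPPA was 3.66-fold lower (3189 and 12178 reads), with HPGD (3.67-fold), TMEM100 (3.31-fold), CA13 (3.25-fold), the red cell membrane gene EPB42 (3.22-fold), the complement gene C1QC (3.12-fold) and UPP1 (3.07-fold). SKOR1, with 1 read in AVC and 24 in VEN, was 3.1-fold lower on this scale. Without the added 1 its ratio of VEN to AVC was 23.1 (95% interval 3.76 to 949).

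Of 22 measured cushion mesenchyme and EMT genes, 10 were at least 2-fold higher and 2 at least 2-fold lower in the chick AVC, with a median log2 ratio of 0.57, at percentile 100 of 10000 random lists matched on expression. The AVC myocardium list had a median of 0.91 (12 of 13 members above 0, percentile 100), the Wnt list 0.65 (percentile 100) and the matrix list 0.57 (percentile 100). The epicardium list, of markers of another cell type, had a higher median than these, 1.3 (6 of 9 members at least 2-fold higher, percentile 100), and whether its cells add to the other medians was not tested. The chamber myocardium list had a median of -0.36 (14 of 15 members below 0, percentile 0.17). Such percentiles do not allow for members that move together. Other lists also reached extreme values, among them the sarcomere list (median 0.30, percentile 100) and the cytosolic ribosomal protein list (-0.41, percentile 0.03). The erythroid list had a median of -1.58, with all 10 members lower in AVC and 8 of them at least 2-fold, alongside a haemoglobin share of 1.34% in AVC and 3.98% in VEN. Every chick list median given here kept its sign when libraries were scaled by their totals. In all, 368 genes were at least 2-fold higher and 157 lower among 11396, so that 70.1% of such genes were higher. Scaled by library totals, which moves the median of all genes to 0.13, the numbers were 500 and 98, or 83.6% higher.

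In the chick OFT, SOX9 (13.8-fold, 362 and 17 reads) and THBS2 (13.3-fold, 575 and 34 reads) had the highest ratios to VEN after adding 1 CPM, followed by COL9A1 (6.32-fold), the forkhead gene FOXS1 (6.24-fold), CHN2 (5.68-fold), ABCG4 (5.52-fold) and NELL1 (5.5-fold). C7ORF16 had 47 reads in OFT and 0 in VEN, at least 15.6-fold higher against a floor of 3 reads and 5.73-fold after adding 1 CPM. Lower in the OFT were GKN2 (7.88-fold), NPPA (7.65-fold, 1592 and 12178 reads), ADAMTS20 (7.36-fold), TBX5 (5.73-fold, 366 and 2132 reads), HSD17B2 (5.06-fold), the angiopoietin gene ANGPT1 (4.31-fold), GJA5 (4.06-fold, 1076 and 4377 reads) and the endothelin receptor gene EDNRB (3.61-fold). The matrix list had a median of 1.12, with 15 of 26 members at least 2-fold higher (percentile 100). The cushion mesenchyme list was at 0.52 (8 of 22 at least 2-fold higher, percentile 100), and the chamber myocardium list -0.69 (6 of 15 at least 2-fold lower, percentile 0). Lists of other cell types moved too, with epicardium at 0.71 (8 of 9 members above 0, percentile 100) and erythroid at -0.50 (10 members, all lower, percentile 0). The outflow tract and second heart field list, with 9 measured members, had a median of 0.07 (percentile 73.8). In all, 406 genes were at least 2-fold higher and 167 lower among 11462.

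Between the chick AVC and OFT, the conduction and inflow regulators TBX5 (6.96-fold, 2493 and 366 reads) and TBX3 (4.5-fold, 283 and 58 reads) were higher in AVC, with FAM5C (8.11-fold), GKN2 (7.5-fold), OTOGL (7.22-fold), ADAMTS20 (5.47-fold), the semaphorin gene SEMA5A (4.42-fold) and HOMER2 (4.27-fold). ELN was 6.13-fold higher in OFT (61 and 442 reads), as were FOXS1 (5.06-fold), the collagen gene COL6A3 (4.95-fold), NELL1 (4.89-fold), FREM1 (3.95-fold), RNF157 (3.75-fold) and TTPA (3.64-fold). SEMA3G, with 3 reads in AVC and 58 in OFT, was 5.2-fold higher in OFT after adding 1 CPM. Without that its ratio of OFT to AVC was 18.5 (95% interval 6.02 to 92.3). The matrix list had a median of -0.64 (percentile 0), and the AVC myocardium list 0.69 (percentile 100). In all, 169 genes were at least 2-fold higher in AVC and 182 in OFT among 11475, so that 48.1% were higher in AVC, against 206 and 146, or 58.5%, when scaled by library totals.

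Set beside each other, most of the genes past the threshold in the mouse fit without a block went the same way in chick, while the rank correlation over all genes was 0.166 or less. Of the 30 genes that passed in the mouse AVC versus VEN and were measured in chick, 24 had the same sign, against a mean of 16.5 and a highest value of 24 in 1000 permutations of the chick values among genes of similar expression. Rspo3 (mouse log2 3.74, chick 3.40), Bmp2 (3.15 and 3.08), Tbx2 (2.96 and 2.59) and Sox9 (2.16 and 3.66) were high in the AVC of both species, and Nppa was low (-2.49 and -1.87). Postn was 6.11-fold higher in the mouse AVC but lower in the chick AVC (log2 -1.01). Eln also had opposite signs in AVC versus VEN (mouse log2 2.204, chick -0.4018). The remaining genes of opposite sign there, named after their values were seen, were Prss35 (2.11 and -0.644), Frzb (1.883 and -0.3459), Col2a1 (2.105 and -0.2854) and Col6a3 (2.235 and -0.1427). Apart from Postn, these genes were less than 2-fold lower in the chick AVC. In OFT versus VEN 85 of 130 genes had the same sign (permuted mean 67.8, highest 84), 70 of the 101 higher and 15 of the 29 lower in the mouse OFT, among them Eln (5.97 and 2.22). In AVC versus OFT it was 12 of 14 (permuted mean 6.9, highest 12), among them Tbx3 (2.86 and 2.17), Tbx5 (2.14 and 2.80) and Eln (-3.76 and -2.62). With mouse calls from the fit with the replicate number as a block, 153 of 249, 428 of 781 and 200 of 300 had the same sign in AVC versus VEN, OFT versus VEN and AVC versus OFT. The permuted means were 130.5, 395.5 and 149, below the values found in each comparison. The highest permuted values were 155, 447 and 176, and AVC versus OFT alone lay above its highest. Penk and Ap3b2 had opposite signs in AVC versus OFT, with chick log2 ratios of 0.74 and -0.36.

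**Figure D3:**
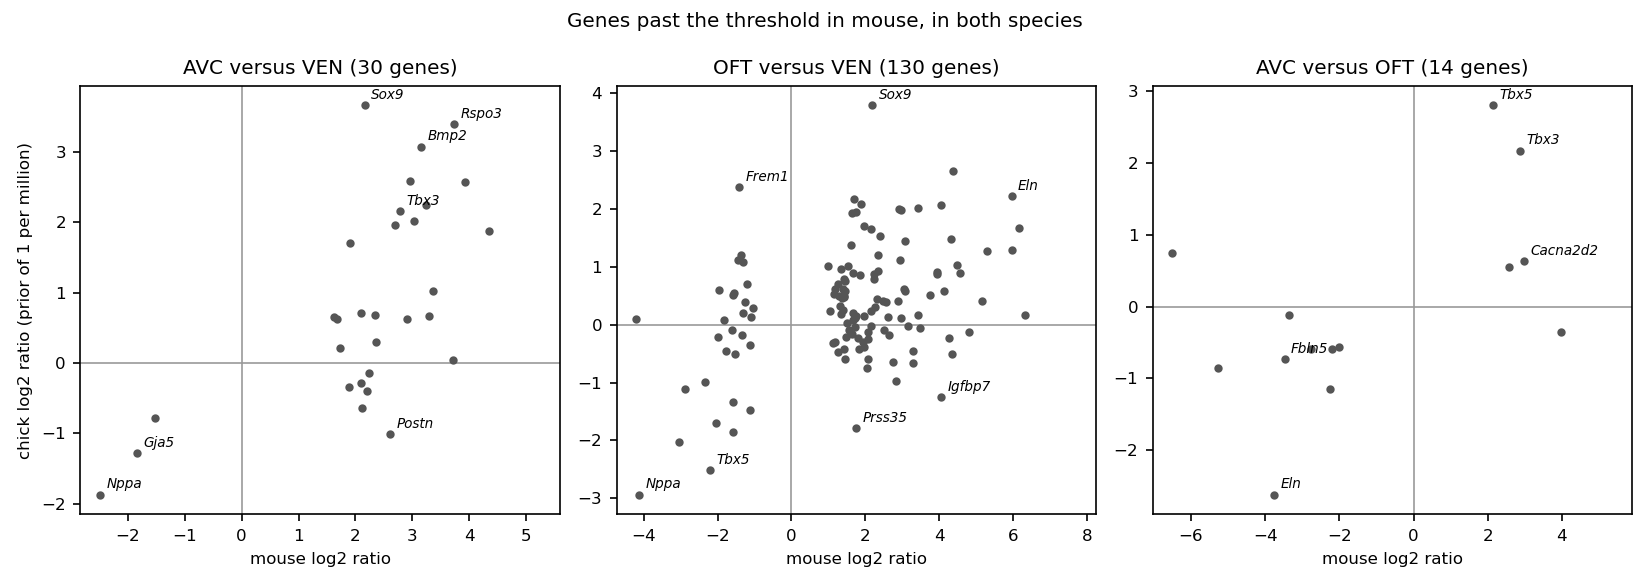
Mouse log2 ratio (horizontal axis) against chick log2 ratio (vertical axis) of the genes past the threshold in mouse, 30 in AVC versus VEN, 130 in OFT versus VEN and 14 in AVC versus OFT. Points in the lower left and upper right parts have the same sign in both species, which held for 24, 85 and 12 genes.

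Over all genes measured in both species the rank correlation across genes was 0.0217 in AVC versus VEN (4302 genes, Pearson r = 0.144), 0.00777 in OFT versus VEN (4309 genes, r = 0.161) and 0.166 in AVC versus OFT (4327 genes, r = 0.18). The central 95% of permuted rank correlations ran from -0.0236 to 0.0364, from -0.0296 to 0.0303 and from -0.0216 to 0.037, so that the AVC versus OFT value alone lay outside its range. With mouse folds from replicate 2 alone that value was 0.0459, the OFT versus VEN value was 0.0331 and the AVC versus VEN value was -0.0184. That OFT versus VEN value, and the AVC versus VEN value with replicate 1 alone, lay above the ranges given here, which were made with both replicates. Genes are not independent replicates, and chick genes were matched to mouse by name.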

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

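The criteria here and the tests of scaling and counting error below were chosen only after the mouse and chick values were seen. Genes are listed that passed in mouse with the same sign in both replicates but were at least 2-fold the other way in chick. For lists the criterion was a camera call in mouse, at least 5 members measured in both species, and medians opposite between species, with the chick median in the outer 5% of random lists. None of these differences between species was tested. In AVC versus VEN this held for Postn (mouse log2 fold change 2.61, chick -1.01). In OFT versus VEN it held for Igfbp7 (mouse 4.06, chick -1.25), Prss35 (1.75 and -1.78), Tshz2 (-1.31 and 1.08), the von Willebrand factor gene Vwf (-1.37 and 1.20), Frem1 (-1.42 and 2.37) and Dsc2 (-1.44 and 1.11), all named after their values were seen.

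Between TMM and library totals the chick log2 ratios of these 7 genes moved by at most 0.141. A change of scaling moves the genes of a comparison nearly alike, and these were chosen for being at least 2-fold apart. The test could thus hardly have come out otherwise. It shows only that the choice between these scalings does not turn their direction. For the 6 genes with at least 50 reads the tables argue against counting error. The p of no change by an exact binomial test, corrected over all 174 mouse calls matched in chick, was at most 1.02e-05. For Tshz2, with 36 reads, counting error cannot be told apart (corrected p = 0.208 by the exact binomial test). Other candidate explanations were not tested and stay open: a chick table name that stands for another member of a gene family, a different stage of development in the species, the spread between chick pools, of which there is 1 library per region, or a true species difference.

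In 5 list comparisons that met this criterion the median over members measured in both species pointed apart. The epicardium list in OFT versus VEN was at -0.55 in mouse and 0.71 in chick, and its mouse call ended without VEN replicate 1 (adjusted p = 0.195). The erythroid list in AVC versus OFT was at 0.56 and -0.56. Its mouse call turned direction without AVC replicate 1 and ended without OFT replicate 2. Those fits cannot tell region from replicate number. Over all 18 mouse members the medians were 0.65 in replicate 1 and 0.32 in replicate 2. The macrophage and leukocyte list in AVC versus VEN was at 1.89 and -0.94. In OFT versus VEN that list had 4 members measured in both species, too few for the criterion, and was at 2.31 and -0.81. The sarcomere list in OFT versus VEN was at -0.22 and 0.22. The retinoic acid list in AVC versus OFT was at 0.16 and -0.19 over 8 shared members, while camera called the 13 mouse genes lower in AVC (adjusted p = 0.0264), the direction of the chick median, although their replicate medians were 0.18 and 0.04. That call ended with each of the 6 mouse libraries left out (adjusted p = 0.0724 to 0.576), so its mouse direction is not settled. With an estimated correlation none of the 5 mouse calls passed (adjusted p = 0.442 for epicardium, 0.472 for erythroid, 0.12 for macrophage and leukocyte, 0.364 for sarcomere and 0.364 for retinoic acid).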

How the results depend on the processing

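Rows with a gene symbol only, and the replicate block combined with that or used for the folds of the cross-species comparison, were chosen after seeing the data. Counts below are for mouse AVC versus VEN, mouse OFT versus VEN, mouse AVC versus OFT, and mouse genes higher in both AVC and OFT than VEN, which were 63, 345, 27 and 50 as reported. With the replicate number as a block they were 751, 2499, 947 and 390, and every gene reported in the 3 comparisons passed too. The block takes up what libraries of a number share, and the common dispersion fell from 0.0585 to 0.0126. The fit without it, set before the data were examined, was kept. With the block and symbols only they were 754, 2356, 994 and 374. Without a filter they were 216, 737, 191 and 137, and by DESeq2 180, 599, 139 and 115. A filter of 10 CPM gave 222 for OFT versus VEN, where fewer genes were tested. Fits of only the 4 libraries compared gave 0 for AVC versus VEN by edgeR (833 at an unadjusted p under 0.05) and so 0 in both, against 374 and 30 in the others. Symbols only gave 41 for AVC versus OFT. Leaving out 1 library, where a region left with 1 is assumed to vary like the others, gave 0 to 52 by edgeR (497 to 905 at an unadjusted p under 0.05), 50 to 419, 0 to 33 (593 to 1448) and 0 to 44.

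List calls were 27 by fry, 0 by fry with the replicate block (smallest adjusted p 0.0591), 57 by camera with that block and 0 by camera with an estimated correlation (27 at an unadjusted p under 0.05), against 56. With 1 library left out, the erythroid list (erythroid, AVC versus VEN) had an adjusted p from 3.85e-10 without AVC replicate 1 to 0.459 without AVC replicate 2, where it turned direction. For erythroid, AVC versus OFT it ran from 3.83e-12 without AVC replicate 2 to 0.774 without AVC replicate 1, where it turned direction. Counts for chick AVC versus VEN, chick OFT versus VEN and chick AVC versus OFT were 913, 953 and 690 with a prior of 0.1, 157, 195 and 82 with 5, and 282, 314 and 195 with at least 100 reads. Rank correlations for mouse and chick AVC versus VEN, mouse and chick OFT versus VEN, and mouse and chick AVC versus OFT were 0.613, 0.299 and 0.486 over genes past the threshold in mouse. At 10 CPM or more OFT versus VEN turned to -0.0126. With single mouse replicates they ran from -0.0184 (without replicate 1) to 0.0807, 0.00411 to 0.0331 and 0.0459 to 0.203. Except where the construction shows it, the cause was not tested. Of 345 named gene results, 100 past the threshold, none turned direction. With the replicate block 150 more passed (155 with symbols only), by DESeq2 53 and without a filter 72, while leaving out OFT replicate 2 ended 82. Pseudocount alternatives apply to normalized values and were not run on counts.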

Other observations

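The tests of the cardiomyocyte share and of the foregut markers below were chosen only after the result was seen, while those of depth, length and GC were set before. Some immune genes also passed in the mouse OFT versus VEN. Of 16 macrophage and leukocyte genes the complement genes C1qc (7.05-fold) and C1qb (6.76-fold) rose and Lyz2 fell in OFT versus VEN (9 rose and 1 fell when adjusted over the list alone). The median was 1.41 (adjusted p = 6.64e-05, and adjusted p = 0.152 with an estimated correlation). In AVC versus VEN the median was 0.78, with no member past the threshold by edgeR and 4 higher when adjusted over the list alone (adjusted p = 1.29e-06, and adjusted p = 0.12 with an estimated correlation). In chick 6 of 6 measured members were lower in AVC than VEN, with a median of -0.74. Of 11 neural genes Stmn2 (13.4-fold) and Tubb3 (8.29-fold) rose and Sox3 fell in OFT versus VEN, where camera did not call the list (adjusted p = 0.0531). Tubb3 (4.99-fold) rose in AVC versus VEN, where the list median was 0.38 (adjusted p = 0.000204, and adjusted p = 0.12 with an estimated correlation). Among retinoic acid genes Crabp1, the receptor gene Rarg (6.5-fold) and the degrading enzyme gene Cyp26b1 (3.04-fold) rose in OFT versus VEN, and among Notch genes Heyl (4.44-fold) and the ligand gene Jag2 (3.81-fold).

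Of 25 guidance genes 3 were higher and 1 lower in AVC than in VEN, and 5 higher and 2 lower in OFT than in VEN. Robo2 (9.71-fold in OFT, 5.05-fold in AVC), Epha3 (7.48-fold in AVC) and Sema3c (4.34-fold in OFT) were among those higher than in VEN, Ntn1 was lower in both and Slit2, named after its values were seen, in OFT (log2 -1.58). Camera called the list in neither comparison (adjusted p = 0.152 in AVC versus VEN and 0.854 in OFT versus VEN). In the chick AVC versus VEN the epicardium list had a median log2 ratio of 1.3, in 1 library per region, with 6 of 9 members at least 2-fold higher, among them TCF21 (log2 2.25) and ALDH1A2 (log2 2.22). In the mouse AVC versus VEN the median was -0.25 and camera did not call the list (adjusted p = 0.144), with Wt1 at 47 ± 23.9 CPM in AVC and 45.8 ± 21.8 in VEN. The difference between species was not tested. Liver genes had a median of -2.0 in OFT versus VEN (adjusted p = 0.00431) and of 1.93 in AVC versus OFT (adjusted p = 0.000217), with no member past the threshold by edgeR (2 and 4 when adjusted over the list alone). The calls ended without OFT replicate 2 (adjusted p = 0.0714) and without AVC replicate 1 (adjusted p = 0.109) respectively, and in neither with an estimated correlation did they pass (0.424 and 0.364). Afp, a fetal liver gene, was at 18.7 ± 21.4 CPM in AVC.

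In mouse, libraries of the same replicate number deviated together: over 14881 features the correlation of replicate differences between regions was 0.548 to 0.65. The tables argue against depth, since the lowest correlation was 0.519 after thinning all libraries to the smallest. They argue against a length or GC trend as the whole. Over the 12356 genes with a transcript the lowest correlation was 0.499, and 0.508 after removing the median per length bin and 0.491 per GC bin. Across these genes the mean replicate difference had a rank correlation of -0.0464 with length and 0.295 with GC content. A candidate explanation is that a number marks hearts collected, staged or sequenced together, which was not tested, and no biological explanation was tested either.

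Of the mesenchyme genes 13 of 30, and of the matrix genes 12 of 34, passed as higher in the mouse OFT than in VEN. Neither list passed by camera with an estimated correlation (adjusted p = 0.104 and 0.0739). A lower share of cardiomyocytes would raise every other cell type alike, yet the medians of the cushion mesenchyme and the endothelium lists stood at least 1.48 apart on the log2 scale in each replicate, which argues against it as the whole cause. The 17 foregut epithelium markers summed in OFT to at most 0.157% of the summed rise of the mesenchyme and matrix genes. Of them 5 were higher in OFT than in VEN in both replicates. Their level in foregut tissue was not measured, so this share cannot tell whether foregut epithelium carried along in dissection contributed. Mesenchyme from outside the heart that borders the OFT, and the difference in tissue between the regions, may contribute and were not tested.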
